A study of Xenopus laevis with 5 samples.

How the data were processed

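Gene expression was measured by RNA sequencing in 5 libraries of Xenopus laevis embryos at stage 10.5, 3 after injection of a control morpholino and 2 after injection of a MOV10 morpholino, with 18 ng injected in each case. Per the labels' protocols, total RNA was extracted with TRIZOL and the libraries were made with a stranded TruSeq mRNA kit. The submitters' processing notes list bcl2fastq 2.17.1.14, FastQC 0.11.4, STAR 2.5.2a and edgeR 3.15.2. The gene models were those of Xenbase on the Xenla9.1 build, per the legend in the deposited annotation table. A MOV10 library with the replicate number 1 was not analysed here, and the MOV10 libraries are called replicates 2 and 3 as in the labels.

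The deposited count files hold, per library, whole-number read counts per gene in the layout of STAR, with a column without strand, a column for the gene's own strand and a column for the reverse strand. In that layout a read counts once and only if it maps to a single place. The column for the reverse strand, which is the sense column for this kind of kit, was used, and it held most of the gene reads in every library. The 4 summary lines of each file name no gene and were left out of library sizes and tests. They held 29.8 to 40.4% of all reads as unmapped, 2.02 to 5.53% as mapping to several places and 48.6 to 57.1% as outside annotated features, of 120128621 to 156177877 reads per library. Reads assigned to genes were 7.51 to 10.4% of the total. Control replicates 1, 2 and 3 had 13515787, 12114894 and 11592035 gene counts, and MOV10 replicates 2 and 3 had 11727654 and 11347400.

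The authors also deposited a table of their own comparison. Its log2 columns, per the file headers, hold the authors' log2 fold change, the mean log2 CPM and the log2 CPM of each library. Its p-value and false discovery rate columns come from the authors' comparison, whose test was not given in the sources used here. A signed fold change is also deposited and was treated as a score, negative where the control was higher. The values per library in that table follow the reverse-strand counts. Its p-values ranked as those of edgeR's glmTreat against a 1.5-fold change run here, with a Spearman correlation of 0.999 across genes, and its log2 fold changes differed from those fitted here by at most 0.0041. Gene symbols, human symbols and coordinates were taken from the deposited annotation table. It named 45098 of the 45099 gene models in the count files, 23101 of them with a symbol that is not only an identifier. The RefSeq table at hand was of another build and was not used for coordinates. No genome sequence was used here.

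Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr and its default minimum count of 10, which left 20049 genes. Libraries were scaled with TMM factors, and the groups were compared with the quasi-likelihood test (glmQLFit and glmQLFTest, two-sided) with the group as the only term. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, with a threshold of 0.05. Levels are CPM after TMM scaling, with the SD between libraries. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. The labels call the libraries biological replicates from separate embryos. The number of embryos per library and the mating pair behind each library were not given in the sources used here.

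Where a group had 0 counts of a gene, the fold change is a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio of summed counts, scaled to library size, is given with an exact binomial 95% interval. Shares of reads in 1 library have Wilson 95% intervals. Sequencing reads are not independent molecules, so intervals and floors cover counting error only. The median log2 fold change of each list was computed again with genes at 0 counts set at their bound. Only the median of the muscle members of the later-stage list moved, from 7.41 to 7.12.

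The rule for named genes, 22 gene lists and the settings were fixed before the data were examined. The rule takes the copies of mov10, then the 12 highest and 12 lowest log2 fold changes among genes past the threshold with a symbol, a mean log2 CPM of at least 2 and both MOV10 libraries beyond all controls. For each list up to 4 members past the threshold with the smallest adjusted p are named as well. Some genes that this rule selects are not reported here. Genes outside the rule were named after their values were seen: myod1, sox17a and ago2, the members given for the tissue groups of the later-stage list, and the genes given for biological process terms, mitochondrial models and homeolog pairs of opposite sign. The lists were built from textbook knowledge of the early frog embryo, its maternal RNAs, signalling pathways, stress responses and later tissues. Some lists share members, such as wnt8a on the ventral, early zygotic and WNT lists. The L and S copies of a gene counted as separate members, so counts of members are not counts of independent genes. A list was tested if at least 5 members were tested. Each list was compared with the other genes by camera (limma 3.58.1, two-sided) with a preset correlation of 0.01 between genes, by camera with an estimated correlation, and by fry, which tests whether the genes of a list move, on balance, 1 way. P-values were adjusted over the 22 lists. Homeolog pairs were genes with the same symbol and the endings L and S, and the share with the same sign was taken over pairs with at least 1 copy past the threshold.

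The procedure was tested on simulated data, 10 draws of counts with the control means, library sizes and spread of the real genes, 3 libraries against 2. There were 200 altered genes, beside the more weakly altered members of a planted list, and 17320 to 17391 genes were tested. With that few altered genes the procedure recovered 1.70% of 2-fold and 47.4% of 4-fold changes. An altered gene that the filter removed counted as not recovered. Of 555 calls 62 were unaltered genes, or 11.2%. An unadjusted p under the threshold was found for 4.68% of unaltered genes, and 3 draws without any altered gene gave at most 1 call each. A planted gene list passed in every draw and 0 of 210 other lists passed. Genes were drawn independently and the lists were random. These draws therefore do not show how camera with the preset correlation behaves for genes that move together.

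The alternatives tried were RLE and upper-quartile factors, no filter on low counts, a filter of at least 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, the column without strand, glmTreat against a 1.5-fold change, the replicate number as a block, each library left out in turn, and the copies of a symbol summed. Scaling to total gene counts was added after seeing the data, as was leaving out each library for the tissue groups of the later-stage list. Terms of biological process, taken from the deposited table's annotation of human symbols, were tested for enrichment with a one-sided hypergeometric test, also chosen after the data were seen.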

Results

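RNA was sequenced from Xenopus laevis embryos at stage 10.5, the early gastrula, after injection of 18 ng of a control morpholino or of a morpholino that blocks translation of MOV10, an RNA helicase associated with the RNA-induced silencing complex. A morpholino is a stable antisense oligonucleotide that binds its target RNA. The control group had 3 libraries and the MOV10 group had 2, and the labels call them biological replicates made from separate whole embryos. The eggs came from 2 mating pairs, and which pair gave which embryo was not given in the sources used here. Between 11347400 and 13515787 reads per library were assigned to genes, and 20049 of 45099 gene models passed the filter on low counts. Levels are given as CPM, read counts scaled to library size, and a floor of 3 counts stood at 0.222 to 0.264 CPM of a library's gene reads. The design implies 1 comparison, MOV10 morpholino against control morpholino, meant to ask how the early embryo's RNA differed when MOV10 translation was blocked. Both groups are labelled stage 10.5, but a difference in true stage cannot be told apart from the morpholino here. No change given below can therefore be credited to the loss of MOV10 alone.

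The target itself was measured first. RNA of mov10.L (Xelaev18012344m.g), at 71893975 to 71921828 on chromosome 2L of the Xenla9.1 build, was higher in the MOV10 group, at 29.4 ± 4.84 CPM (SD, n = 2) against 5.19 ± 2.25 (SD, n = 3) in the controls. The log2 fold change was 2.49 ± 0.40 (SE), with an adjusted p = 0.00180 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Raw counts were 105, 33 and 71 in the control libraries and 349 and 275 in the MOV10 libraries. A second gene model matched to human MOV10, LOC100494487.L (Xelaev18011958m.g, 2L, 50451493 to 50507674), had few reads and did not pass the test, with a log2 fold change of -1.03 ± 1.45 (SE) and an edgeR adjusted p = 0.599. Its S copy had 0, 2, 7, 3 and 22 counts in the 5 libraries and was not tested. Because a translation-blocking morpholino acts on the protein and not on the RNA level, these RNA values check neither the labels nor the knockdown.

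The highest genes in the MOV10 group included many of skeletal and cardiac muscle. No control library had a read of tnnc1.S (a troponin C) or coro6.L (a coronin). These genes were at least 242-fold and 274-fold higher in the MOV10 group, against a floor of 3 counts over the 3 controls together. Myosin-binding protein gene mybpc3.S had 2 counts in all controls together and 3198 in both MOV10 libraries, a ratio of 2963 (95% counting interval 820 to 24480). The sarcomere genes klhl41.S and mypn.S, each with 1 control count, had ratios of 3010 (539 to 118950) and 2500 (448 to 98820). A ratio of 2176 (390 to 86010) was found for itga7.L, the laminin-binding integrin chain of muscle, which also had 1 control count. Genes of other kinds were among the 12 highest as well. The Toll-like receptor gene tlr7.L was at least 533-fold higher, ccdc27.S at least 269-fold, the pyrimidine-degrading enzyme gene dpys.L at least 250-fold and the nuclear receptor gene pparg.S at least 195-fold. For ndrg1.L, with 1 control count, the ratio was 2528 (453 to 99918), and its MOV10 libraries differed widely from each other (64.4 ± 69.5 CPM, SD, n = 2). Several of these values rested unequally on the libraries. Without MOV10 replicate 3 the bounds were 113-fold for coro6.L and 308-fold for tlr7.L, and the ratios were 1172 (209 to 46451) for itga7.L, 1853 (512 to 15321) for mybpc3.S, 1657 (296 to 65587) for mypn.S and 599 (106 to 23809) for ndrg1.L. Without MOV10 replicate 2 coro6.L was at least 436-fold higher, and ndrg1.L had a ratio of 4465 (800 to 176510). Leaving out control replicate 1 made the bounds of the 6 genes without control reads 1.61 times smaller, as fewer control reads then stand behind the floor, with coro6.L at least 170-fold, tlr7.L 330-fold, tnnc1.S 150-fold, ccdc27.S 167-fold, dpys.L 155-fold and pparg.S 121-fold higher. It also left mybpc3.S with a ratio of 1838 (508 to 15180) and itga7.L with 1349 (242 to 53333). As it held the only control count of klhl41.S, mypn.S and ndrg1.L, they were then at least 622-fold, 517-fold and 522-fold higher, and itga7.L at least 499-fold without control replicate 2.

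The list of later-stage differentiation genes, fixed before the data were examined, showed the same direction. Of its 49 tested members 26 rose, 0 fell and 23 did not pass the test, and 27 rose when adjusted over the list alone. Fast-muscle myosin light chain genes mylpf.S and mylpf.L rose by 9.86 ± 0.28 and 10.31 ± 0.38 on the log2 scale (SE), myl1.S by 9.84 ± 0.40 and troponin T gene tnnt3.S by 7.82 ± 0.27. In CPM, tnnt3.S stood at 9.90 ± 2.58 (SD, n = 3) in the controls and 2229 ± 66.9 (SD, n = 2) in the MOV10 group. Camera with a preset correlation placed the list above the other genes (adjusted p = 1.15e-11), and the call did not hold at adjusted p = 0.111 with an estimated correlation. When the list was divided by tissue after its values were seen, all 12 muscle members rose, and their summed level was 14070 ± 1115 CPM (SD, n = 2) against 223 ± 167 (SD, n = 3), with 84.2, 408 and 178 CPM in the 3 controls. Among 13 neural members 5 rose, while pax6.L had 1.07 ± 0.97 and elavl3.L 0.75 ± 0.83 on the log2 scale (SE), neither past the threshold. The MOV10 libraries stood apart in pax6.S, at 9.22 CPM in replicate 2 and, under the floor, at 0.0945 CPM in replicate 3. Of 9 multiciliated-cell members 3 rose (dnai1.L, tekt2.L and tekt2.S), of 4 posterior hox members 3 (hoxc6.L, hoxc6.S and hoxb9.S), and of 6 neural crest members 1 (sox9.L). Without MOV10 replicate 2 the neural members were 4 higher and 2 lower, and without MOV10 replicate 3 they were 6 higher. The posterior hox members that rose were 1 without MOV10 replicate 3 and 2 without control replicate 3. The L and S copies of a gene count as separate members, so the 12 muscle members are not 12 separate genes. Members of these tissue groups were named after their values were seen.

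**Figure D1:**
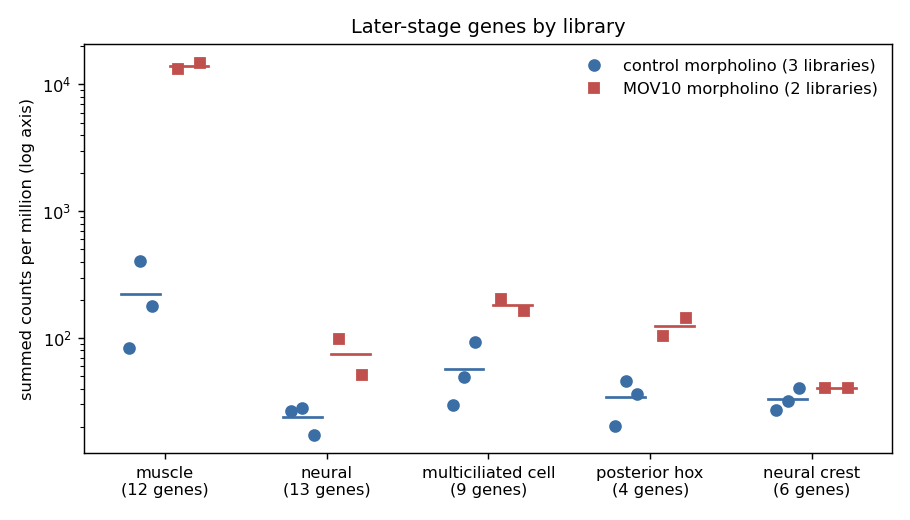
Summed CPM (log axis) of the tested later-stage genes in each library, grouped by tissue, with 3 control libraries as circles, 2 MOV10 libraries as squares and group means as lines. The muscle genes sum to 223 CPM on average in the controls and to 14070 in the MOV10 group, while the neural crest genes sum to 33.1 and 40.5.

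Across all tested genes 4899 were higher and 3544 lower with the MOV10 morpholino, together 42.1% of those tested, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. A change of at least 2-fold was fitted for 4549 of the higher and 2947 of the lower genes. Correlations of log2 CPM across genes, which are not independent replicates, were 0.947 to 0.951 within the controls, 0.926 between the MOV10 libraries and 0.695 to 0.729 between the groups. The MOV10 libraries also showed more gene models with at least 1 read (26811 and 26093, against 23190 to 24144). In 436 of the called genes the controls had 0 counts, and in 79 the MOV10 libraries had 0. With total gene counts as the scale, added after seeing the data, 4358 genes were higher and 4357 lower.

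Genes of the uncommitted embryo and of early zygotic transcription fell more often than they rose. The pluripotency factor genes pou5f3.2.L and pou5f3.2.S, homologs of mammalian Oct4, fell 49.9-fold and 37.6-fold. In the MOV10 group pou5f3.2.L was at 9.89 ± 3.84 CPM (SD, n = 2), and in the controls at 494 ± 28.7 (SD, n = 3; edgeR adjusted p = 1.29e-05). Of 28 tested members of the pluripotency and competence list 12 fell, 2 rose and 14 did not pass; 13 fell and 2 rose when adjusted over the list alone. The related pou5f3.1.L and the homeobox gene ventx1.2.L, also on this list, fell 5.46-fold and 3.44-fold. Camera gave this list an adjusted p = 6.01e-04, and an adjusted p = 0.331 with an estimated correlation. Among 39 early zygotic genes 19 fell, 3 rose and 17 did not pass, and 20 fell and 3 rose when adjusted over the list alone. The gastrula-specific gs17.L fell 11.7-fold, from 911 ± 102 CPM (SD, n = 3) to 78.0 ± 13.6 (SD, n = 2), and gdf3.S, a TGF-beta ligand gene, fell 17.6-fold (28.8-fold without MOV10 replicate 3). For the early zygotic list camera gave an adjusted p = 1.17e-04, and an adjusted p = 0.256 with an estimated correlation. Both lists fell in the libraries in which the 12 muscle genes rose.

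The 12 lowest named genes also held bmp7.2.L, a bone morphogenetic protein gene, which fell 71.6-fold from 213 ± 12.2 CPM (SD, n = 3) to 2.97 ± 0.724 (SD, n = 2). The secreted antagonist gene cer1.S (Cerberus) fell 34.2-fold, dkkx.L (Dickkopf family) 32.7-fold and the Nodal co-receptor gene tdgf1.3.L 28.4-fold. A maternal-effect gene, zar1.S, fell 37.9-fold, and the sphingosine phosphate receptor gene s1pr5.S fell 79.8-fold, with 4 counts left in both MOV10 libraries together. With 2 or 3 MOV10 counts, cox5b.2-like.L had a control to MOV10 ratio of 96.3 (26.5 to 798), igfbp5.S of 73.4 (24.9 to 357) and icmt.S of 46.4 (15.7 to 226). Without MOV10 replicate 2 the falls were 41.2-fold for s1pr5.S, 48.9-fold for tdgf1.3.L, at least 89.7-fold for zar1.S and at least 23.2-fold for icmt.S, and the ratio of cox5b.2-like.L was 48.1 (lower limit 13.2). Without MOV10 replicate 3 zar1.S fell 19.2-fold and cox5b.2-like.L at least 32.2-fold, and the ratios were 110 (19.7 to 4368) for igfbp5.S and 23.3 (7.87 to 113) for icmt.S. The change of menf.1-like.1.1 rested on unequal controls (18.0 ± 28.1 CPM, SD, n = 3), and it had a log2 fold change of -5.37 ± 1.83 (SE) with an edgeR adjusted p = 0.0433. That call ended without control replicate 3, where the log2 fold change was -2.01 (edgeR adjusted p = 0.137). It also ended without MOV10 replicate 2 (-4.74, edgeR adjusted p = 0.146) and without MOV10 replicate 3 (-6.51, edgeR adjusted p = 0.0935), and the adjusted p ranged from 1.41e-04 to 0.369 over 15 alternatives.

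More patterning genes fell than rose on both the dorsal and the ventral list. Of 45 tested organizer and dorsal mesoderm genes 18 fell, 4 rose and 23 did not pass, with the same counts when adjusted over the list alone. The BMP antagonist gene chordin fell in both copies, chrd.1.L 12.6-fold (249 ± 65.9 to 19.8 ± 1.74 CPM, SD, n = 3 and n = 2) and chrd.S 6.18-fold, and lhx1.S fell 9.94-fold. The organizer list had a camera adjusted p = 1.24e-04, and an adjusted p = 0.331 with an estimated correlation. Of 45 ventral and BMP response genes 19 fell, 5 rose and 21 did not pass, again with the same counts adjusted over the list alone. The ventral homeobox gene ventx1.1.S fell 10.1-fold, msx1.S 5.37-fold, and the BMP pseudoreceptor gene bambi 4.19-fold in its S copy and 3.19-fold in its L copy. The ventral list had a camera adjusted p = 5.00e-04, and an adjusted p = 0.302 with an estimated correlation. The 12 muscle genes of the later-stage list rose in the same libraries.

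Germ layer genes were divided. Among 52 mesoderm genes 20 fell, 5 rose and 27 did not pass, with the same counts adjusted over the list alone. The segmentation gene mespb fell in its S and L copies 7.42-fold and 5.81-fold, and the retinoic acid synthesis gene aldh1a2.S fell 14.6-fold, while tcf15.S, a gene of somites, rose 34.7-fold. Mesoderm genes had a camera adjusted p = 2.56e-04, and an adjusted p = 0.210 with an estimated correlation. The muscle determination genes myod1.L and myod1.S, also on this list, had log2 fold changes of 1.13 ± 0.46 and 0.72 ± 0.42 (SE) and did not pass the test. Of 38 endoderm genes 9 fell, 4 rose and 25 did not pass, with the same counts adjusted over the list alone. In this list frzb2.S fell 7.86-fold, while sox17a.L and sox17a.S, core endoderm factors, had 0.13 ± 0.42 and 0.48 ± 0.39 on the log2 scale (SE), neither past the threshold. The endoderm call was near the threshold at a camera adjusted p = 0.0364, and an adjusted p = 0.509 with an estimated correlation. It ended without MOV10 replicate 2 (0.333) and without control replicate 3 (0.0635), in a range of 0.00504 to 0.509 over 17 alternatives. The muscle genes of the later-stage list rose in the same libraries.

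In the ectoderm, 17 of 52 non-neural and epidermal genes fell, 10 rose and 25 did not pass, with the same counts adjusted over the list alone. The epidermal regulator genes tfap2a.L, foxi4.2.L and foxi4.2.S fell 6.02-fold, 7.14-fold and 6.52-fold, and the tight junction gene cldn6.S rose 22.5-fold. Epidermal genes had a camera adjusted p = 0.0257, and an adjusted p = 0.414 with an estimated correlation. That call ended without MOV10 replicate 2 (0.0624) and without MOV10 replicate 3 (0.109), in a range of 0.0123 to 0.414 over 17 alternatives. Of 58 neural plate genes 23 fell, 6 rose and 29 did not pass, with the same counts adjusted over the list alone. Geminin gene gmnn.S fell 4.74-fold, and N-cadherin gene cdh2.L rose 5.49-fold. Neural plate genes had a camera adjusted p = 7.33e-04, and an adjusted p = 0.407 with an estimated correlation. Both ectodermal lists were measured in the libraries in which the muscle genes rose.

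**Figure D2:**
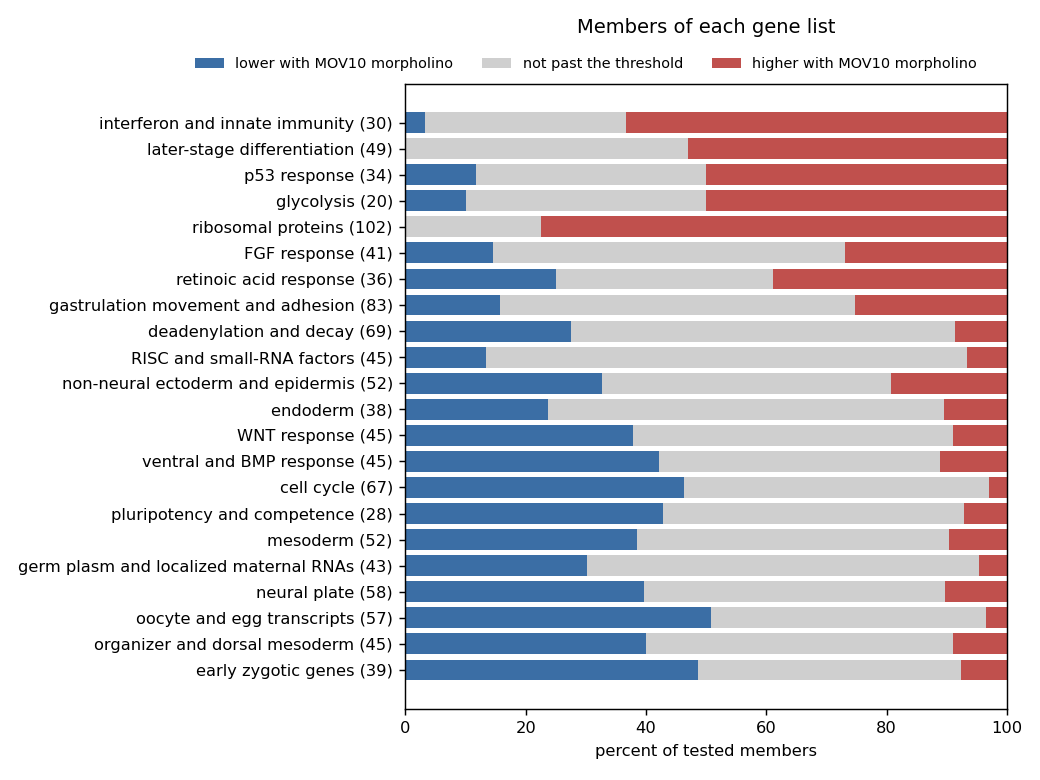
Percent of tested members of each gene list that were lower, higher or not past the threshold with the MOV10 morpholino, with the number tested in parentheses and lists ordered by median log2 fold change. Of the 102 ribosomal protein genes 79 are higher and 0 lower, and of the 57 oocyte and egg transcripts 29 are lower and 2 higher.

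Signalling lists differed in their outcome. Of 45 WNT response genes 17 fell, 4 rose and 24 did not pass, with the same counts adjusted over the list alone. The WNT target genes sp5.L and sp5.S fell 21.4-fold (34.4-fold without MOV10 replicate 2) and 13.1-fold, the WNT-inactivating enzyme gene notum.L 20.8-fold and hoxd1.L 16.4-fold. For the WNT list camera gave an adjusted p = 5.21e-04, and an adjusted p = 0.414 with an estimated correlation. The retinoic acid list divided, with 14 genes higher, 9 lower and 13 not past the test among 36, or 16 higher and 10 lower adjusted over the list alone. Its camera adjusted p was 0.945 with the direction down, although its median and mean log2 fold changes were 0.38 and 1.16. The degrading enzyme gene cyp26a1.L fell 4.45-fold and hoxd1.S by 2.91 on the log2 scale. Among 41 FGF response genes 11 rose, 6 fell and 24 did not pass (11 and 6 adjusted over the list alone), and the camera adjusted p was 0.328. The immediate early genes fos.L, fos.S and ier2.L rose 78.7-fold (183-fold without control replicate 1), 23.8-fold and 4.43-fold, and Brachyury gene t.L fell 6.41-fold. Of 83 gastrulation movement and adhesion genes 21 rose, 13 fell and 49 did not pass, with the same counts adjusted over the list alone and a camera adjusted p of 0.785. Non-muscle myosin gene myh9.L rose 7.62-fold, fibronectin receptor gene itga5.L 5.56-fold, and the small GTPase gene rhob 13.9-fold in its S copy and 12.8-fold in its L copy. The WNT list fell in the libraries in which the muscle genes of the later-stage list rose, from 223 to 14070 CPM summed, and the other signalling lists were measured in the same libraries.

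Maternal transcripts and cell cycle genes fell more often than they rose. Of 57 oocyte and egg transcripts 29 fell, 2 rose and 26 did not pass, with 30 lower and 2 higher adjusted over the list alone. The oocyte linker histone gene h1foo fell 24.6-fold in its L copy and 6.26-fold in its S copy, the zona pellucida gene zp3.S 13.4-fold (26.8-fold without MOV10 replicate 3), and cyclin B gene ccnb1.2.S 3.39-fold. The oocyte list had a camera adjusted p = 1.84e-05, and an adjusted p = 0.302 with an estimated correlation. Among 43 germ plasm and localized maternal RNAs 13 fell, 2 rose and 28 did not pass, with 13 lower and 1 higher adjusted over the list alone. The germ cell regulator gene nanos1.L fell 27.0-fold (16.8-fold without MOV10 replicate 2 and 70.5-fold without MOV10 replicate 3), velo1.L 8.01-fold, mmachc.L 3.88-fold and wnt11b.L 3.36-fold. Germ plasm RNAs had a camera adjusted p = 0.00212, and an adjusted p = 0.331 with an estimated correlation. Of 67 cell cycle genes 31 fell, 2 rose and 34 did not pass, with the same counts adjusted over the list alone. Cyclin genes ccnb2.L, ccnb2.S, ccne1.L and ccna2.L fell 6.23-fold, 5.11-fold, 4.57-fold and 3.41-fold. Cell cycle genes had a camera adjusted p = 7.27e-05, and an adjusted p = 0.414 with an estimated correlation. The muscle genes rose in the libraries in which these 3 lists fell.

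Neither of the lists fixed for MOV10's own pathways passed camera. With both directions together, members of both lists were called less often than all tested genes, of which 42.1% passed. Of their members 36 of 45 and 44 of 69 did not pass. By direction the deadenylation and decay list differed. Of its 69 members 19 fell, a larger share than the 3544 of all 20049 genes, and 6 rose, a smaller share than the 4899 of 20049. Of 45 RISC and small-RNA factors 3 rose, 6 fell and 36 did not pass (3 and 2 adjusted over the list alone), and camera gave 0.243 after adjustment. The RNA helicase gene ddx5, a partner of microRNA processing, fell 2.71-fold in its L copy (3891 ± 410 to 1438 ± 70.2 CPM, SD, n = 3 and n = 2) and 2.58-fold in its S copy. The microRNA-processing nuclease gene drosha.L rose 3.70-fold, and lin28a.L, which binds let-7 precursors, rose 4.05-fold. The Argonaute copies ago2.L and ago2.S had -1.17 ± 0.70 and 0.10 ± 0.41 on the log2 scale (SE), neither past the threshold. Of 69 deadenylation and decay genes 6 rose, 19 fell and 44 did not pass (6 and 18 adjusted over the list alone), and camera gave 0.0959 after adjustment. The nuclear exonuclease gene xrn2.S fell 3.47-fold, while the antiproliferative gene btg1.S rose by 1.58 on the log2 scale and its L copy fell by 0.66 (edgeR adjusted p = 0.0277), and ttc37.L and skiv2l.L, of the Ski complex, rose 4.86-fold and 4.81-fold.

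Stress, immune, glycolytic and ribosomal protein genes rose more often than they fell. Of 34 p53 response genes 17 rose, 4 fell and 13 did not pass, with 18 higher and 4 lower adjusted over the list alone. The stress kinase gene plk2 rose 45.9-fold in its S copy and 14.6-fold in its L copy, and ccng1.S rose 9.73-fold. The p53 list had a camera adjusted p = 7.33e-04, and an adjusted p = 0.331 with an estimated correlation. Of 30 interferon and innate immunity genes 19 rose, 1 fell and 10 did not pass, with 20 higher and 1 lower adjusted over the list alone. Complement gene c3.L rose 34.9-fold, from 117 ± 11.4 CPM (SD, n = 3) to 4098 ± 756 (SD, n = 2). The NF-kappa-B inhibitor gene nfkbia.L rose 10.2-fold and complement factor B gene cfb.L 8.17-fold, and cfb.S, with 1 control count, had a ratio of 308 (54.5 to 12224), which was 191 (33.8 to 7580) without control replicate 1 and at least 71.0 without control replicate 3. Immune genes had a camera adjusted p = 3.06e-05, and an adjusted p = 0.150 with an estimated correlation.

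Of 20 glycolysis genes 10 rose, 2 fell and 8 did not pass, with the same counts adjusted over the list alone. Phosphofructokinase gene pfkp.L rose 56.5-fold, pyruvate kinase genes pkm.S and pkm.L 7.22-fold and 4.88-fold, and aldoa.L 3.77-fold. Glycolysis genes had a camera adjusted p = 0.0237, and an adjusted p = 0.449 with an estimated correlation. The call ended without MOV10 replicate 3 (0.132), in a range of 0.00776 to 0.449 over 17 alternatives. Of 102 ribosomal protein genes 79 rose, 0 fell and 23 did not pass, with 82 higher and 0 lower adjusted over the list alone. The changes were small beside those of muscle genes, with rpsa.L 3.52-fold, rpl19.L 3.40-fold, rps21.L 2.88-fold and rps6.S 2.31-fold higher. Ribosomal protein genes had a camera adjusted p = 3.90e-05, and an adjusted p = 0.586 with an estimated correlation. These 4 lists, the p53 and immune lists included, rose in the libraries in which the 12 muscle genes rose. In all, 17 of the 22 lists passed camera with the preset correlation, 12 of them lower and 5 higher, and 0 passed with an estimated correlation, while fry gave 16.

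Xenopus laevis is allotetraploid, and many genes have an L and an S copy on homeologous chromosomes. Among 5055 pairs with both copies tested, 2971 had at least 1 copy past the threshold, and in 2314 of these, 77.9%, the log2 fold changes had the same sign (95% exact binomial interval 76.4 to 79.4, for counting error alone). Among all 5055 pairs the share was 69.4%, and copies with unrelated signs would give 50% for either set. Where both copies passed, in 1150 pairs, 1054 went the same way and 96 went opposite ways. Across the pairs Spearman's correlation of the 2 log2 fold changes was 0.52, and genes are not independent replicates. Reads that fit both copies equally well are not counted for either under unique mapping, so values of near-identical copies are uncertain.

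**Figure D3:**
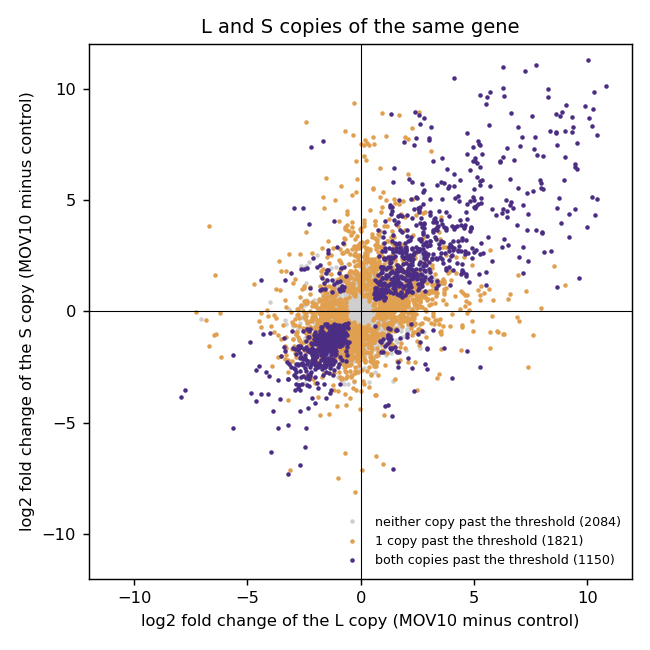
Log2 fold change (MOV10 minus control morpholino) of the S copy against that of the L copy for 5055 pairs, each point 1 pair, coloured by how many copies passed the threshold. Most of the 1150 pairs with both copies past the threshold lie at the lower left and upper right, where both signs are alike, and 96 lie where the signs differ.

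The authors' deposited table listed 19421 genes, with 3975 higher and 2461 lower at a false discovery rate under 0.05. All 6436 of these were also past the threshold here, with the same direction. The authors' values follow the same counts, and their p-values ranked as those of a test against a 1.5-fold change. Such a test is stricter than the one used here, so this overlap was largely fixed in advance and the numbers of calls are not alike in threshold. With 3 libraries against 2, simulated data with the same depth recovered 1.70% of 2-fold and 47.4% of 4-fold changes among 200 altered genes, and 11.2% of the calls were unaltered genes. Small changes that did not pass are therefore not shown to be absent. Both the recovered shares and the share of unaltered genes among calls depend on how many genes are altered. A comparison with 42.1% of genes called was not simulated, so neither share carries over to these data. In the real comparison 79 of 102 ribosomal protein genes were called higher and 0 lower, at a list median log2 fold change of 0.74.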

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

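All tests in this part were chosen after the results they concern were seen. Groups of 3 and 2 libraries are too small for a test of single outlying libraries, and the design has 1 contrast, so the signals given first come from outside the counts used for the comparison. The muscle and p53 patterns that follow come from those counts. On the strand opposite to the one counted, 11.7% of the gene reads of MOV10 replicate 2 (95% Wilson interval 11.7 to 11.7) and 10.7% of those of MOV10 replicate 3 (10.7 to 10.7) were found, above the 6.15, 6.92 and 7.89% of the control libraries. MOV10 replicate 2 had 5.53% of its reads mapped to several places (8640343 of 156177877), against 2.06, 2.31 and 2.02% in the controls and 2.13% in MOV10 replicate 3. No explanation of the multimapping share was tested.

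The rise of the opposite-strand share was weighed against less strand-specific libraries and against reads at few loci. For the median gene among 1039 with at least 1000 counts, the opposite-strand share was 0.205, 0.240 and 0.229% in the controls and 0.276 and 0.244% in the MOV10 libraries, a ratio of 1.16 between the group means where the overall share had a ratio of 1.61. This argues against less strand-specific libraries as the cause. The 5 gene models with the largest rise held 99.4% of it, the first alone, a model without a name, 73.6%, and a model matched to mitochondrial ND6, which is encoded opposite to most mitochondrial genes, 18.4%. The rise is thus consistent with reads at a few loci, and why these loci rose in both MOV10 libraries was not tested.

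The second pattern is the rise of muscle genes with the fall of early embryonic genes, and the 12 muscle genes, 11 of which also had reads in the controls, were led in the MOV10 group by actc1.L, actc1.S and tnnt3.S at 3511, 3119 and 2229 CPM. Muscle RNA mixed into otherwise unaltered embryos would lower all other genes by a common factor, but the log2 fold changes of 280 members of the fallen lists with at least 10 CPM in the controls had an SD of 1.43 against a root mean square standard error of 0.38 (range -5.64 to 4.50), which argues against it as the whole cause. Embryos of a later stage than labelled may also show this pattern. The test, written after the values were seen, asked for a lower quartile over 1 in every tissue group. Against a later stage it asked that no upper quartile outside muscle showed a rise. Neither outcome could be reached with the values already seen. The lower quartile of the multiciliated-cell members was -0.25, and the upper quartile of the neural members was 3.24. The test therefore has no weight for or against a later stage. Beside these groups, 41 of 75 gene models of anterior/posterior pattern specification rose and 9 fell, and 29 of 57 oocyte and egg transcripts fell and 2 rose. These genes were not part of the test. Posterior hox members of the later-stage list had a median log2 fold change of 1.87, against 7.41 for muscle (7.12 with myog.S at its bound). The median was 0.47 for the multiciliated-cell members (-0.040 without MOV10 replicate 2, 1.44 without control replicate 3) and 0.21 for the neural crest members (0.041 without control replicate 2, 0.48 without control replicate 3). For the neural members it was 1.49 (quartiles 0.75 to 3.24), but 1.04 without MOV10 replicate 2 (-2.31 to 3.39) 1.99 without MOV10 replicate 3 (1.34 to 3.25) and 2.52 without control replicate 1 (1.04 to 3.22), with summed levels of 98.6 and 51.2 CPM in replicates 2 and 3, so this group rested on unequal libraries. Stage cannot be told apart from the morpholino here, because both MOV10 libraries show the rise of muscle genes (13282 and 14858 CPM summed) and no stage series was used, and the loss of MOV10 itself stays open as well, untested.

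The third pattern is the rise of p53 response and innate immune genes. A reaction to the MOV10 oligonucleotide apart from the loss of MOV10 could account for it, and the p53 list had a median log2 fold change of 1.23. With 1 MOV10 oligonucleotide and no rescue in the samples analysed here, such a reaction cannot be told apart from the loss of MOV10 or from a difference in stage.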

How the results depend on the processing

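Scaling to total gene counts, and leaving out libraries for the tissue groups of the later-stage list and for genes named outside the fixed choice, were chosen after seeing the data. The number of higher genes ranged from 3718 (without MOV10 replicate 2) to 5318 (limma-voom), beside 4899, and that of lower genes from 2424 (glmTreat) to 4357 (total gene counts), beside 3544. Against TMM the median log2 fold change of all genes shifted by -0.15 with upper-quartile factors and by -0.20 with total gene counts, and 51.9% of the calls with upper-quartile factors were higher genes, beside 58.0%, while total gene counts gave 4358 higher and 4357 lower. It shifted by 0.25 without the filter on low counts, where 32011 genes were tested. With copies of a symbol summed, the number of genes higher with MOV10 morpholino was 3853 and the number of genes lower with MOV10 morpholino was 2874. Where 1 MOV10 library was left out, the lone library was assumed to vary like the controls.

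Of 1573 comparisons of 105 named genes with an alternative, 1568 kept direction and side of the threshold and 0 turned direction. Apart from the mov10 copies, these genes were selected for small p-values or extreme fold changes. Their stability therefore says little about typical calls. Across all tested genes, 6909 to 7108 of the 8443 calls were made again in the same direction without a control library. With the replicate number as a block 6827 were. Fewer were made again without a MOV10 library, where 1 library stood for that group. The fold change or bound of 26 of the 105 moved by over 1.5 times without a library, for 19 of them without a MOV10 library. The 5 comparisons that did not keep both were all of menf.1-like.1.1, beside a log2 fold change of -5.37. By edgeR it had -5.37 (adjusted p = 0.0561) with glmTreat, -2.01 (0.137) without control replicate 3, -4.74 (0.146) without MOV10 replicate 2 and -6.51 (0.0935) without MOV10 replicate 3. By limma-voom it had -3.60 (adjusted p = 0.369), and its adjusted p ranged from 1.41e-04 to 0.369. For the 22 lists, 335 of 374 comparisons kept both. The number of lists that passed was 0 with an estimated correlation, where 17 calls ended, and 15 to 17 with a library left out. Other ended calls, by camera's adjusted p, were endoderm with limma-voom (0.0909), total gene counts (0.0522), without control replicate 3 (0.0635) and without MOV10 replicate 2 (0.333), non-neural ectoderm with limma-voom (0.0909) and without MOV10 replicate 2 (0.0624) or 3 (0.109), and glycolysis without MOV10 replicate 3 (0.132). By fry, endoderm (0.217) and non-neural ectoderm (0.0581) did not pass and FGF response did (0.0305), and deadenylation and decay passed without the filter on low counts (0.0228). Over 17 alternatives these p-values ranged from 0.00504 to 0.509 for endoderm, 0.0123 to 0.414 for non-neural ectoderm, 0.00776 to 0.449 for glycolysis, 0.0305 to 0.739 for FGF response and 0.0228 to 0.449 for deadenylation and decay.

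The retinoic acid list, with no call, turned direction without the filter on low counts (0.904), with at least 1 CPM in 2 libraries (0.995), with limma-voom (0.784), with glmTreat (0.771), by fry (0.292) and with some libraries left out (0.343 to 0.950 over all 5). Gastrulation movement and adhesion, also with no call, turned with some libraries left out (0.249 to 0.951 over all 5). Among the tissue groups of the later-stage list, the median log2 fold change of the multiciliated-cell members turned to -0.040 without MOV10 replicate 2, in a range of -0.040 to 1.44 over all 5 libraries left out. The other groups kept their sign, with 7.32 to 7.59 for muscle, 1.04 to 2.52 for neural, 1.60 to 2.13 for posterior hox and 0.04 to 0.48 for neural crest members. The share of homeolog pairs with the same sign was 79.8% with glmTreat, beside 77.9%. Apart from the smaller number of samples where a library was left out and the larger number of genes without the filter, the cause was not tested.

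Control and MOV10 replicates 2 and 3 share a number, and no label says that it marks a pair. With the replicate number as a block 4118 genes were higher and 3098 lower, the retinoic acid list turned direction (0.981), and no call of a named gene or list ended. As a check of the pairing, deviations from the group means correlated at 0.071 for the libraries numbered 2 and at 0.020 for those numbered 3. Control replicate 1 and MOV10 replicate 3, with unlike numbers, had 0.054. With 2 MOV10 libraries their deviations mirror each other, so these values cannot decide whether the numbers mark pairs. Depth limits genes near the floor of 3 counts, where fold changes are bounds or wide ratios.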

Other observations

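The enrichment of biological process terms, the mitochondrial shares, the choice of terms and genes named in this part and their values with a library left out followed after the results were seen. Terms of mRNA splicing and RNA export were enriched among lower genes, while rRNA processing was enriched among higher genes, with 84 of 185 symbols where 57.1 were expected (hypergeometric adjusted p = 0.00165), and 67 of the 84 were ribosomal protein genes. In rRNA processing 41 symbols had a lower copy. Of 196 human symbols annotated to mRNA splicing via the spliceosome, 122 had a lower copy, where 48.7 were expected, with an adjusted p = 4.68e-26 by a hypergeometric test over 1036 terms. Among their 337 gene models 164 fell, 22 rose and 151 did not pass edgeR's test, with a median log2 fold change of -0.67. The splicing factor gene sf1.S fell by 2.70 ± 0.25 on the log2 scale (SE), hnrnph1.S fell by 2.37 ± 0.22, srsf4.L fell by 2.30 ± 0.24 and rbmx.L fell by 1.77 ± 0.17, while the helicase gene ddx39b.L rose by 3.80 ± 0.26. RNA export from the nucleus was also enriched among lower genes, with 30 of 44 symbols where 10.9 were expected (adjusted p = 7.76e-07), and 40 of its 85 gene models fell, 8 rose and 37 did not pass. Terms near MOV10's own pathways were enriched in both directions. Of 76 symbols annotated to gene silencing by RNA 36 had a lower copy and 11 a higher one, where 18.9 lower were expected (adjusted p = 0.00185). Among those 36 were 11 of nuclear pore proteins, 9 of RNA polymerase subunits and 2 that the RISC list names, DGCR8 and TNRC6B. The gene models matched to DGCR8 carry no frog symbol and were not in the test of that list. For exonucleolytic RNA hydrolysis 13 of 21 symbols had a lower copy, where 5.22 were expected (adjusted p = 0.0208). Nonsense-mediated decay was enriched among higher genes, with 71 of 105 symbols where 32.4 were expected (hypergeometric adjusted p = 2.74e-12), and 67 of the 71 were ribosomal protein genes. In this term 13 symbols had a lower copy.

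Terms of the extracellular matrix, of complement and of the body axis were enriched among higher genes. Of 81 symbols annotated to extracellular matrix organization 50 had a higher copy, where 25 were expected (adjusted p = 1.32e-06). Among their 126 gene models 63 rose, 11 fell and 52 did not pass edgeR's test, and the cartilage and notochord collagen gene col2a1 rose by 6.68 ± 0.50 in its S copy and 5.14 ± 0.45 in its L copy. Complement activation had 11 of 13 symbols where 4.02 were expected (adjusted p = 0.00590), and of 23 gene models 16 rose, 1 fell and 6 did not pass, with c8b.L at 10.03 ± 0.65, c8a.L at 8.79 ± 0.44 and cfd.L at 5.61 ± 0.25 on the log2 scale. Without MOV10 replicate 3 c8b.L was at 9.24 and c8a.L at 8.12, c8b.L was at 10.80 without control replicate 3, and col2a1.L was at 5.72 without control replicate 2. For anterior/posterior pattern specification it was 26 of 42 where 13.0 were expected (adjusted p = 0.00205), and of 75 gene models 41 rose, 9 fell and 25 did not pass, with hoxa3.S at 5.67 ± 0.44, hoxa3.L at 5.25 ± 0.51 and hoxb8.S at 2.74 ± 0.32. In all, 24 terms were enriched among higher and 20 among lower genes of 9765 symbols. A symbol counted if any of its copies was called, so a symbol with more gene models counted more easily, and 220 counted in both directions. The test was not adjusted for expression level, gene length or the number of gene models of a symbol. In 10 draws of random calls 0 gave an enriched term, and a planted term was found in all 10. Random calls were drawn per symbol under the test's own assumption, and leave out correlation between genes and the number of gene models per symbol. These draws therefore do not check the test for genes that move together or for symbols with several gene models. The genes of the terms above were measured in the libraries in which the 12 muscle genes of the later-stage list rose.

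Mitochondrial gene models took a larger share of the gene counts in the MOV10 libraries. Those matched to ND1, ND5 and ATP6 together held 9.27, 11.3 and 13.0% of the gene counts in the controls and 17.3 and 15.3% in the MOV10 libraries. The ATP6 model had a log2 fold change of 0.92 ± 0.17 (SE, edgeR adjusted p = 0.00314) and the ND5 model 0.76 ± 0.25 (edgeR adjusted p = 0.0357), while the ND1 model, at 0.36 ± 0.20 (edgeR adjusted p = 0.179), did not pass.

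Among the 96 homeolog pairs whose copies both passed the threshold in opposite directions were dscaml1, with a log2 fold change of 4.02 in its L copy and -2.99 in its S copy, the AMP-activated kinase gene prkaa2 with -2.55 and 4.62, col13a1 with 2.34 and -3.57, and gas6 with -2.26 and 3.94. The call of dscaml1.S ended without MOV10 replicate 2 (-2.18, edgeR adjusted p = 0.0706) and without control replicate 3 (-2.70, edgeR adjusted p = 0.0657). That of prkaa2.S ended without MOV10 replicate 3 (3.90, edgeR adjusted p = 0.0851), and that of prkaa2.L without MOV10 replicate 2 (-2.08, edgeR adjusted p = 0.0894) and without control replicate 3 (-2.41, edgeR adjusted p = 0.0505). Without MOV10 replicate 3 gas6.S rose 7.98-fold, and dscaml1.S and prkaa2.L, with 1 to 3 MOV10 counts left, had control to MOV10 ratios with counting intervals of 6.34 to 1431 and up to 48.8. Without control replicate 2 prkaa2.S had a MOV10 to control ratio of 54.2 (14.5 to 455). The difference between copies was not itself tested.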
